A study of Mus musculus with 8 samples.

How the data were processed

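RNA was extracted with TRIzol from CT26 cells grown in RPMI medium with serum, and 1 μg per sample went into an mRNA library kit from Yeasen for Illumina sequencing, per the labels. The 8 libraries fall into 2 genotypes of 4, WT and Tead1/4 knockout, taken from each sample's title and genotype label. HISAT2, StringTie and the GRCm38 build are named in the submitters' processing notes, without versions or settings. The program that counted reads, its settings, its use of strand and its handling of reads that match several genes are not given in the sources used here.

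The authors deposited raw counts per gene as whole numbers, in 2 tables with identical values, so only 1 was used and the planned refit on the other table would change nothing. Each table has 26642 rows and 8 library columns, all of which map to a sample: 22036 rows are annotated genes and 4606 are loci whose identifiers mark them as not annotated. Of the annotated identifiers, 22022 were found in GENCODE release M21 on GRCm38, which gave the coordinates printed here, and 21914 are protein coding, so long non-coding RNAs are largely not analysed here. Fewer rows hold a count of 1 than of 2 in each library (101 to 225 against 288 to 981), so read mates may have been counted separately, and intervals or floors from these counts cover counting error at best. If strand was not used, overlapping and antisense genes cannot be told apart. 19 symbols occur on more than 1 row.

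Total counts per library ranged from 29679405 to 32774905, at which 3 counts correspond to 0.0915 to 0.101 CPM. Where all libraries of a genotype had a count of 0, the fold is given as a lower bound against 3 counts per library; where a genotype had 1 to 3 counts in all, the ratio is given with its 95% exact binomial (Clopper-Pearson) interval. Before averaging, libraries of each genotype were compared pairwise by a chi-square over rows with at least 20 counts. The chi-square per degree of freedom was between 34.7 and 257, so no pair agreed within sampling noise, and each library counts as 1 replicate. WT replicates 1 and 4 (34.7) and 2 and 3 (35.0) were closer to each other than the remaining WT pairs (201.5 to 241.5). Whether such a pair shares a culture or preparation is not given in the labels. If it does, WT holds fewer independent units than 4, and the p-values are too small.

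Genes were filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), scaled with TMM factors and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), two-sided, for knockout minus WT, with no covariates. The Benjamini-Hochberg adjusted p had to be under 0.05, and a size limit of 2-fold was applied as a separate count. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.294. CPM are TMM-scaled, computed here and not by the authors. The targeted genes were also compared by an exact two-sided permutation test of log2 CPM over 70 assignments. On counts simulated with the real means and library sizes for this comparison (12529 genes tested, 50 changed at each fold), the test recovered 2% of genes changed 1.5-fold, 36% at 2-fold, 94% at 4-fold and 100% at 8-fold, with 5 false calls, and made 1 call when no change was simulated. Each gene was drawn independently, and far fewer genes changed than were called in the real data, so these shares do not carry over to it.

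Before the data were examined, 40 gene lists of pathways, cell types and RNA quality were fixed, with the tests, the alternatives and the rule for named genes. Lists with at least 5 tested members (36) were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and repeated with an estimated correlation and with fry. The genes named are Tead1 to Tead4, Yap1 and Wwtr1, then the 12 with the largest positive and the 12 with the largest negative log2 fold change among genes past the threshold, with a mean of at least 10 CPM in the higher genotype, no overlap between genotypes and a symbol that is not a clone or predicted-gene name. From each list past camera, and from the YAP target and Hippo lists, the 4 members with the smallest p are named, and from any other list 2, which may be left out where none passed. Up to 3 members going against a list's direction by at least 2-fold may be named. Other names are marked as chosen after their values were seen. Of the 12 largest increases 11 are described, and 2 genes are not reported here.

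The alternatives were DESeq2's size factors, upper-quartile factors and library size only as scaling; no filter or a minimum of 5 CPM in 4 libraries; DESeq2 1.42.0 (Wald test) and limma-voom as tests; the replicate number as a block; an adjusted p under 0.01; a test against a log2 fold change of 0.5; and each library left out in turn. Those added after the data were seen were annotated genes only, the removal of the 13 mitochondrially encoded genes, the mean level of the G2/M list as a covariate, and the removal of a loess trend on transcript GC content and length, which 11764 tested rows have. Figures were drawn with matplotlib 3.10.9.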

Results

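Messenger RNA was sequenced from CT26 cells, a mouse colon carcinoma line, either unedited (WT, 4 libraries) or carrying a knockout of Tead1 and Tead4 (4 libraries). Tead1 and Tead4 encode DNA-binding partners of YAP and TAZ, the effectors of the Hippo pathway. Total counts per library lay between 29679405 and 32774905. A count above 0 was found in 14566 to 15430 genes and loci of the WT libraries. Knockout replicates 2, 3 and 4 had 17759 to 17948 and knockout replicate 1 had 14345. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels are CPM, counts scaled to the library's effective size, as mean ± SD with n = 4 per genotype. Fold changes are knockout minus WT on the log2 scale with their standard error (SE). Adjusted p-values of genes come from edgeR's quasi-likelihood test and those of gene lists from camera, both two-sided.

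Both targeted mRNAs were lower in the knockout libraries but remained detected. Tead1 (ENSMUSG00000055320; GRCm38 chromosome 7, 112679318 to 112906807, plus strand) was at 67.5 ± 12.4 CPM (SD, n = 4) in the knockout libraries and at 206 ± 80.8 CPM in WT. The log2 fold change was -1.61 (SE 0.27, edgeR adjusted p = 0.00217). Its 4 knockout values, 51.2, 64.8, 76.3 and 77.8 CPM, all lay below the 4 WT values, 319, 155, 142 and 209 CPM (exact two-sided permutation p = 0.0286 over 70 assignments, the smallest they can give). Tead4 (ENSMUSG00000030353; chromosome 6, 128224288 to 128300823, minus strand) was at 29.3 ± 6.08 CPM against 47.8 ± 12.3 CPM in WT. The log2 fold change was -0.71 (SE 0.22, edgeR adjusted p = 0.0261). The knockout values of Tead4 were 25.9, 23.3, 31.2 and 37.0 CPM and overlapped the WT values of 52.1, 36.7, 39.4 and 63.2 CPM (exact two-sided permutation p = 0.0571). The call for Tead4 was lost when WT replicate 1 or 4 or knockout replicate 2 or 3 was left out (adjusted p = 0.0601, 0.0664, 0.0800 and 0.0606). It was also lost with upper-quartile factors or library size only as the scaling (adjusted p = 0.0692 and 0.0800). With the G2/M level as a covariate, an alternative added after the data were seen, the calls for both genes were lost (Tead1 -2.004, adjusted p = 0.0719; Tead4 -1.06, adjusted p = 0.143). Counts cover the whole gene and the labels do not give the edited part, so these levels do not measure the loss of either protein. Among the other family members, Tead2 (log2 fold change -0.07, adjusted p = 0.756) and Tead3 (-0.31, adjusted p = 0.136) did not pass the test. Of the genes for the cofactors, Yap1 rose from 122 ± 12.02 to 191 ± 15.4 CPM (log2 fold change 0.65, SE 0.13, edgeR adjusted p = 0.00507), and Wwtr1, which encodes TAZ, did not pass (0.08, adjusted p = 0.776). Tead2 was on the positive side with upper-quartile factors or library size only (log2 fold change 0.10 under both).

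**Figure D1:**
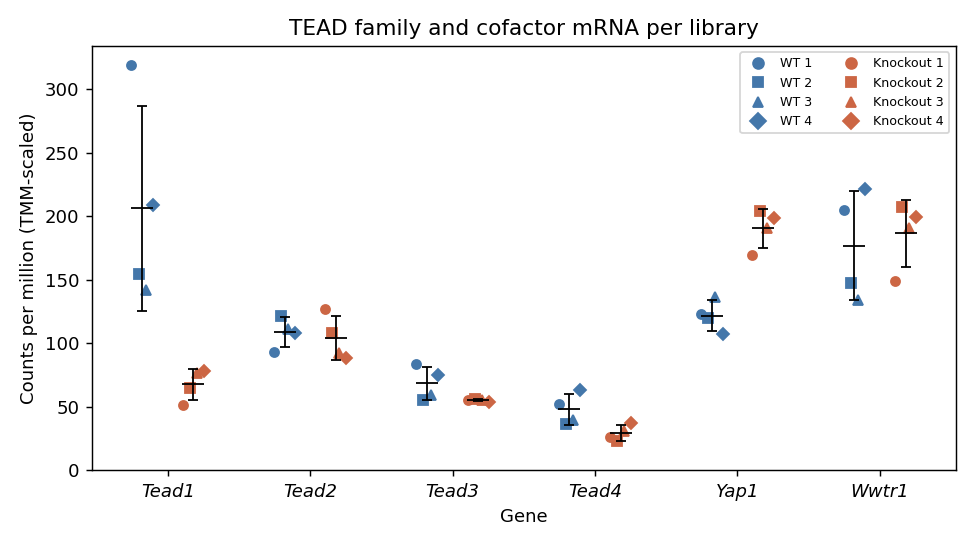
CPM (y axis, TMM-scaled counts, from 0) of the TEAD genes, Yap1 and Wwtr1 (x axis) in each of the 4 WT (blue) and 4 knockout (orange) libraries, with the mean and SD of each genotype as black bars. Tead1 lies at 51.2 to 77.8 CPM in the knockout libraries and at 142 to 319 CPM in WT, while the Tead4 values of the genotypes overlap.

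The question the series poses is how the transcript profile differs between knockout and unedited cells. It differed widely: of 13265 genes and loci tested, 5513 (41.6%) changed at an adjusted p under 0.05, 2779 higher and 2734 lower in the knockout libraries. A change of at least 2-fold was found for 2969, with 1833 higher and 1136 lower. Annotated genes accounted for 4939 of the calls (2341 higher, 2598 lower) and unannotated loci for 574 (438 higher, 136 lower). The 4 knockout values lay wholly above or below the 4 WT values for 5404 rows, or 40.7%, against 2.86% by chance. The near-even split rested on the scaling: 50.4% of the calls were higher with TMM factors, 64.6% with upper-quartile factors and 63.5% with library size only. Both moved the median log2 fold change of all rows from 0.02 to 0.20. Removing a trend with GC content and transcript length gave 40.6%, over 11764 rows that are all annotated genes. Annotated genes only, without that removal, gave 49.8%. Without knockout replicate 3 the lower genes numbered 1768. With the mean level of the G2/M list per library as a covariate, which itself differs between the genotypes, 555 genes were called (454 higher, 101 lower).

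**Figure D2:**
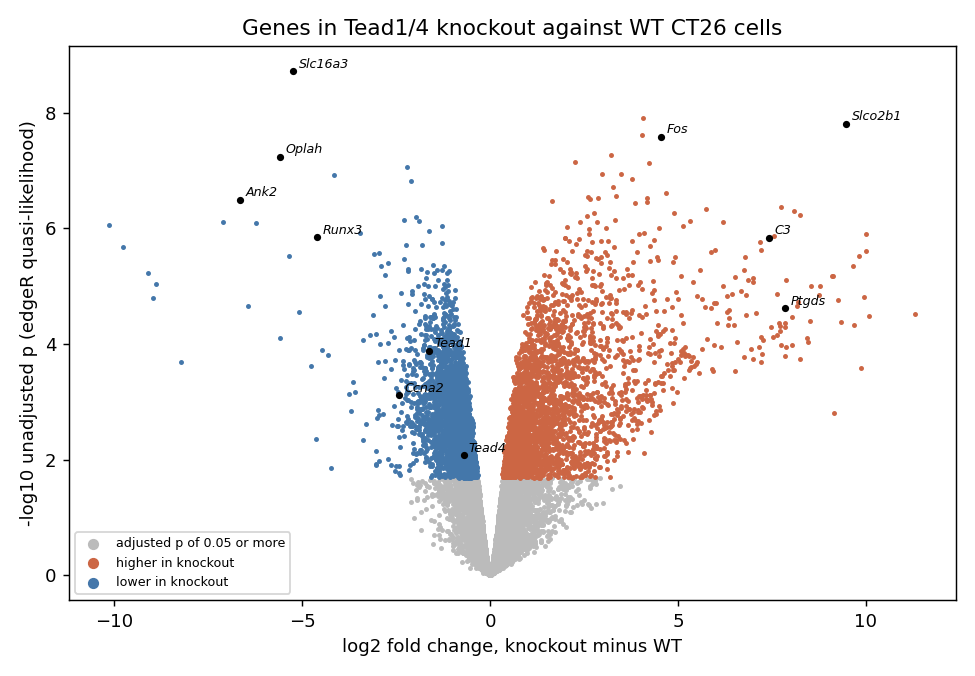
Fitted log2 fold change (x axis, knockout minus WT) against the -log10 unadjusted p of edgeR's quasi-likelihood test (y axis) for 13265 genes and loci, with 2779 called higher (orange), 2734 called lower (blue) and the rest in grey. Black points mark named genes, and for a gene at 0 in a genotype the fitted position depends on the prior count.

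The increases described next are from the 12 largest among called genes with a mean of at least 10 CPM in the knockout libraries and no overlap between genotypes. Larger fitted increases at lower levels are therefore left out here. The means in WT were all under 1 CPM. Complement C3, the central component of the complement cascade, rose from 0.924 ± 0.547 to 159 ± 87.8 CPM (log2 fold change 7.43, SE 0.73, edgeR adjusted p = 0.000322). Slco2b1, an organic anion transporter, had 2 counts over all WT libraries and 2034 over the knockout libraries, a ratio of 884 with a 95% exact counting interval of 244 to 7300. Ptgds, a prostaglandin D2 synthase, reached 103 ± 84.4 CPM from 0.432 ± 0.499 (log2 fold change 7.86, SE 1.06). Ces1d, a carboxylesterase, reached 90.9 ± 65.0 CPM from 0.306 ± 0.371 (8.17, SE 1.09). Agt, which encodes angiotensinogen, rose by 6.998 (SE 0.82), Rarres2, which encodes chemerin, by 6.50 (SE 0.95), and Akr1c18 by 6.20 (SE 0.57) on the log2 scale. Selenop, a selenium carrier, rose by 6.01 (SE 0.79), Mmp3, a stromelysin, by 5.99 (SE 0.62), Slfn2 by 5.96 (SE 0.79) and Fmo2 by 7.86 (SE 1.28). The edgeR adjusted p of these 7 genes lay between 0.000247 and 0.00206. That all 4 knockout libraries lay above all 4 WT libraries for each of these 11 genes was a condition of the choice, not a result. Knockout replicate 1 was the lowest knockout library for 10 of them, all but Mmp3. It stood at 32.1 CPM for C3 (185 to 234 in the other knockout libraries), 11.2 for Ces1d (84.7 to 170), 23.2 for Ptgds (73.9 to 222) and 0.727 for Fmo2 (7.21 to 29.3). For Rarres2 it was at 5.66 CPM (25.03 to 39.73) and for Selenop at 16.9 (46.7 to 80.5). Levels this low in WT and the spread between knockout libraries may both leave the folds loosely fixed, and their parts were not separated. With 1 library left out, the log2 fold change of Slco2b1 lay between 9.104 and 11.893, the top value being set by the prior count, since WT is then at 0. It lay between 7.687 and 9.082 for Ces1d and between 6.741 and 8.651 for Fmo2, which had 5 counts in WT. The ranges were 7.167 to 8.415 for Ptgds, 6.07 to 7.479 for Rarres2, 5.38 to 6.507 for Mmp3 and 5.531 to 7.184 for Slfn2. The other 4 genes stayed within 0.5 of their main value. Ces1d, Akr1c18, Fmo2 and Slfn2 belong to families of similar genes. How shared reads were counted is not given in the sources used here, so their levels are uncertain.

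The decreases described next are the 12 largest among called genes with a mean of at least 10 CPM in WT and no overlap between genotypes. Genes at lower levels in WT are left out here, among them Lonrf1, which was at least 49.7-fold lower. Ank2, an ankyrin, fell from 14.9 ± 3.10 to 0.142 ± 0.118 CPM (log2 fold change -6.66, SE 0.55, edgeR adjusted p = 0.000184). Oplah, the 5-oxoprolinase of glutathione turnover, fell from 235 ± 116 to 4.85 ± 0.687 CPM, which is 48.3-fold lower (SE 0.39 on the log2 scale, adjusted p = 0.000109). Slc16a3, which encodes the lactate exporter MCT4, fell from 54.0 ± 9.66 to 1.43 ± 0.423 CPM, 37.7-fold lower (log2 fold change -5.24, SE 0.25, adjusted p = 2.5e-05). Runx3, a transcription factor, was 24.2-fold lower (18.8 ± 8.79 to 0.773 ± 0.302 CPM, adjusted p = 0.000322). Smaller decreases were found for Gpr141 (log2 fold change -2.96, SE 0.31), the mitochondrial carrier Ucp2 (-2.79, SE 0.37), the actin-binding protein gene Nexn (-2.73, SE 0.43) and Arsj (-2.71, SE 0.30). The remaining 4 were the cell cycle genes E2f8 (-2.62, SE 0.48), Ccna2 (-2.41, SE 0.51), Cenpf (-2.37, SE 0.46) and Pmf1 (-2.35, SE 0.52). With 1 library left out, they ranged from -3.151 to -2.355, -3.172 to -2.148, -2.965 to -2.102 and -3.1 to -2.075, in that order. Knockout replicate 1 was the highest knockout library for all 4, such as Ccna2 at 219.5 CPM (41.6 to 86.1 in the others). That all 4 knockout libraries lay below all 4 WT libraries for each of these genes was a condition of the choice, not a result.

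Target genes of YAP, TAZ and TEAD did not pass the list test. Of 23 members tested, 4 rose and 3 fell (4 and 3 adjusted over the list alone). They had a median log2 fold change of 0.01, a mean of -0.04 and a camera adjusted p of 0.811. Lats2, a Hippo kinase and feedback target, fell from 136 ± 19.2 to 76.6 ± 8.25 CPM (edgeR adjusted p = 0.00302), and Dock5 fell by 0.74 on the log2 scale (adjusted p = 0.0049). Crim1 rose by 0.88 (adjusted p = 0.0136) and Tgfbr2 by 0.54 (adjusted p = 0.00931). The other members called, named after their values were seen, were Cyr61, Amotl1 and Asap1. Cyr61, a matricellular protein gene and common readout of YAP activity, rose from 238 ± 67.6 to 410 ± 94.4 CPM (adjusted p = 0.0227). Amotl1 rose by 0.74 (adjusted p = 0.0194) and Asap1 fell by 0.87 (adjusted p = 0.0204). Without WT replicate 1, and under the stricter filter on low counts, the list's direction turned positive (camera adjusted p = 0.960 and 0.787). In the list of Hippo pathway components and TEAD cofactors, 3 of 31 members rose and 7 fell (3 and 6 adjusted over the list alone), with a camera adjusted p of 0.205. Besides Tead1, Lats2 and Yap1, Fat1, an atypical cadherin, changed with a log2 fold change of -1.25 (328 ± 117 to 138 ± 10.3 CPM, adjusted p = 0.00334). The third increase, beside Yap1 and Amotl1, was Frmd6 (0.655), named after its value was seen.

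Of 36 lists with at least 5 tested members, 21 passed camera with its preset correlation of 0.01, 14 upward and 7 downward. With a correlation estimated for each list none of the 21 calls held (lowest adjusted p = 0.302, 4 lists at an unadjusted p under 0.05). The fry test, which asks whether a list moves one way without comparing it with other genes, passed 25: it lost ATF4 and gained the Hippo, apoptosis, mesenchymal, growth factor and muscle lists. Of the 35 splits of the libraries into 4 and 4, the real one included, 3 put at least 21 lists past camera, and the other 2 of these still set 3 WT libraries and 1 knockout library against the rest. With the G2/M level as a covariate 7 calls were lost: AP-1 (camera adjusted p = 0.157), NF-kB (0.316), G1/S (0.0598), G2/M itself (0.417), collagens (0.488), glycolysis (0.296) and sterol synthesis (0.0598). The same covariate gained a call for oxidative phosphorylation as higher (1.06e-05, median log2 fold change 0.713 with it and 0.021 without). The stricter filter on low counts ended those of the integrin (0.0528), ATF4 (0.0604) and fibroblast lists (0.0759).

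Genes of the interferon response and of antigen presentation rose together. Of 34 type I interferon response genes, 30 rose and 1 fell (31 and 1 adjusted over the list alone). The median was 2.66 on the log2 scale, with a camera adjusted p = 2.35e-11 and adjusted p = 0.395 with an estimated correlation. Ifit3, an antiviral effector, rose from 1.38 ± 0.845 to 55.0 ± 19.9 CPM (edgeR adjusted p = 0.000247). Zbp1, a sensor of Z-form nucleic acid, rose from 0.972 ± 0.741 to 34.8 ± 6.91 CPM (adjusted p = 0.000258). Ifih1, the RNA sensor MDA5, rose by 2.42 on the log2 scale (SE 0.30) and Rsad2 by 3.24 (SE 0.45). The member that fell was Cgas, a cytosolic DNA sensor (log2 fold change -1.60, adjusted p = 0.00282). The WT libraries were far apart for this list. Its mean log2 level, relative to all 8 libraries, was -1.99, -0.16, -0.89 and -2.53 in WT replicates 1 to 4. It lay between 1.20 and 1.56 in the knockout libraries. In the interferon gamma response list 17 of 22 members rose and none fell (17 and 0 adjusted over the list alone). The median was 2.57 on the log2 scale, with a camera adjusted p = 9e-07 and adjusted p = 0.395 with an estimated correlation. Among the increases were the interferon-inducible GTPase genes Gbp4 (log2 fold change 4.47, SE 0.48), Iigp1 (5.64, SE 0.73, 5.23 to 6.802 with 1 library left out), Tgtp1 (4.13, SE 0.55) and Gbp9 (3.62, SE 0.50). MHC class I antigen presentation genes showed 19 increases and 2 decreases among 23 (19 and 2 adjusted over the list alone). The median was 1.89 on the log2 scale, with a camera adjusted p = 9e-07 and adjusted p = 0.395 with an estimated correlation. The class I heavy chain gene H2-K1 rose from 49.4 ± 13.5 to 199 ± 19.8 CPM. H2-T22 rose by 2.25, H2-T23 by 4.33 and the immunoproteasome subunit Psmb8 by 3.24 on the log2 scale, with edgeR adjusted p of 0.00133 or less. The chaperone genes Calr and Pdia3, named after their values were seen, were the decreases (-0.96 and -0.64). The WT libraries were far apart for the interferon gamma and MHC class I lists too. The mean log2 level of the interferon gamma list was -1.59, -0.28, -0.85 and -2.10 in WT replicates 1 to 4. That of the MHC class I list was -1.14, -0.32, -0.49 and -1.53. Several members of the Gbp, Tgtp, Ifit and H2 families share similar sequence and their individual levels are uncertain for that reason.

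Chemokine and cytokine genes rose in 13 of 19 tested cases, of 35 listed, with no decrease (13 and 0 adjusted over the list alone). The median was 2.20 on the log2 scale, with a camera adjusted p = 0.000684 and adjusted p = 0.302 with an estimated correlation. Cxcl1, a neutrophil attractant, rose from 2.09 ± 1.11 to 20.6 ± 4.37 CPM (edgeR adjusted p = 0.000531). Il34 rose by 1.97 and Il15 by 2.32 on the log2 scale (adjusted p = 0.00123 and 0.00245). Il18, at 0 in all WT libraries, was at least 7.04-fold higher. Immune checkpoint and surface ligand genes rose in 8 of 13 tested cases, of 25 listed, with no decrease (9 and 1 adjusted over the list alone). The median was 1.38 on the log2 scale, with a camera adjusted p = 0.00449 and adjusted p = 0.302 with an estimated correlation. They included Cd47, a signal against phagocytosis (103 ± 12.3 to 267 ± 74.6 CPM), and the costimulatory ligand Cd80 (log2 fold change 1.57, SE 0.25). Also higher were Cd274, which encodes PD-L1 (2.24 ± 0.623 to 8.08 ± 2.26 CPM, edgeR adjusted p = 0.00232), and Cd276 (0.91, SE 0.16). NF-kB target genes showed 13 increases and 3 decreases among 21 (13 and 4 adjusted over the list alone). The median was 0.79 on the log2 scale, with a camera adjusted p = 0.00752 and adjusted p = 0.507 with an estimated correlation. Members that rose included C3, Cxcl1, Lcn2 (5.08, SE 0.59) and Birc3 (1.83, SE 0.27). The decreases were Rel, an NF-kB subunit gene (-1.15), and, named after their values were seen, Vcam1 and Sod2 (-0.62 and -0.49).

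Genes of cell division fell. In the list of G1/S and DNA replication genes 28 of 33 members fell and none rose (30 and 0 adjusted over the list alone). The median was -1.35 on the log2 scale, with a camera adjusted p = 7.8e-11 and adjusted p = 0.395 with an estimated correlation. E2f2, a transcription factor of S-phase entry, went from 28.6 ± 1.57 to 6.29 ± 2.32 CPM (edgeR adjusted p = 0.00053). The cyclin gene Ccne2 went from 64.4 ± 11.01 to 21.3 ± 8.28 CPM (adjusted p = 0.00206). The replication genes Orc1 and Pole had log2 fold changes of -2.20 and -1.68. Of 33 G2/M and mitosis genes 24 fell and none rose (29 and 0 adjusted over the list alone). The median was -1.57 on the log2 scale, with a camera adjusted p = 2.29e-10 and adjusted p = 0.395 with an estimated correlation. The proliferation marker Mki67 went from 941 ± 397 to 208 ± 128 CPM (adjusted p = 0.00514) and cyclin gene Ccna2 from 529 ± 151 to 99.3 ± 82.4 CPM (adjusted p = 0.00556). Ect2, required for cytokinesis, went from 285 ± 51.2 to 61.2 ± 47.2 CPM and Cenpf from 360 ± 85.2 to 69.5 ± 49.9 CPM. The knockout libraries were far apart for these lists. The mean log2 level of the G2/M list, relative to all 8 libraries, was 0.48 in knockout replicate 1, -0.81 in replicate 2, -1.54 in replicate 3 and -1.86 in replicate 4, against 0.81 to 1.11 in WT. MYC target and ribosome biogenesis genes fell in 25 of 31 cases with none rising (29 and 0 adjusted over the list alone). The median was -0.85 on the log2 scale, with a camera adjusted p = 2.39e-09 and adjusted p = 0.395 with an estimated correlation. Dkc1 of the telomerase and snoRNP complexes had a log2 fold change of -1.99 (SE 0.30), the nucleolar protein gene Nop58 -1.43 (SE 0.21), the spermidine synthase gene Srm -1.61 (SE 0.27) and Rrs1 -0.94 (SE 0.15).

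**Figure D3:**
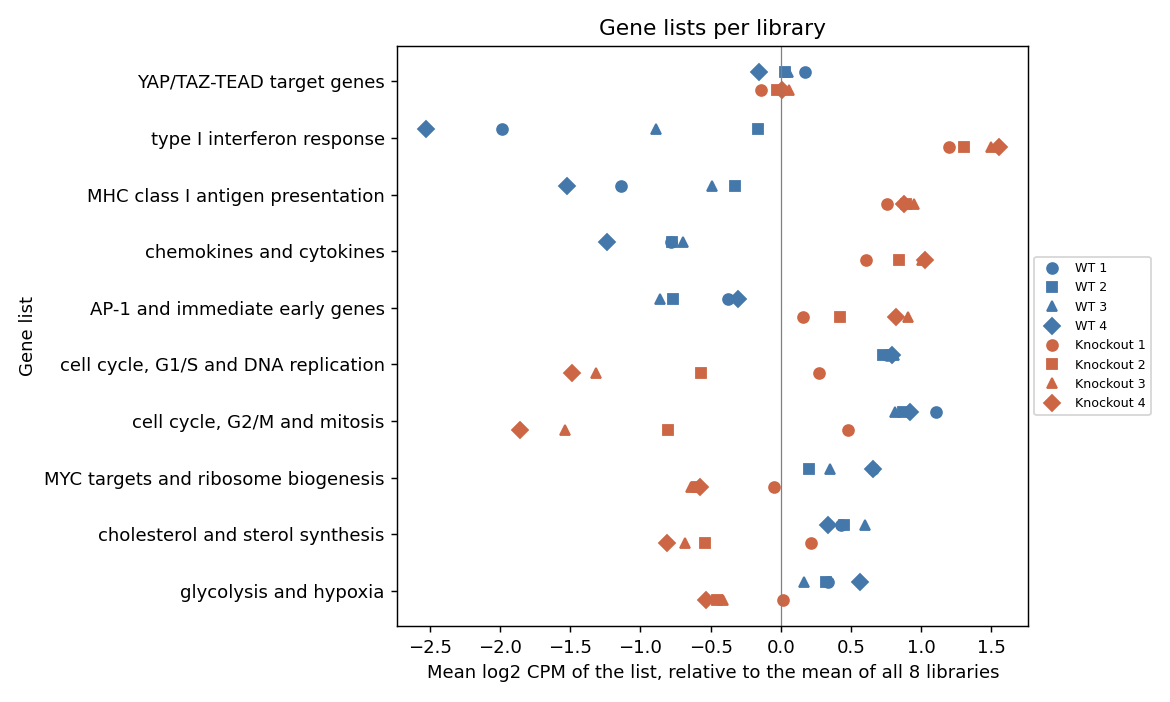
Mean log2 CPM of 10 gene lists (y axis) in each of the 4 WT (blue) and 4 knockout (orange) libraries, relative to the mean of all 8 libraries (x axis, log2 units). The type I interferon list lies between 1.20 and 1.56 in the knockout libraries and between -2.53 and -0.16 in WT, and the G2/M list spans 0.48 to -1.86 within the knockout libraries.

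Immediate early genes, which respond to growth factor and stress signals, were mostly higher, as 13 of 20 AP-1 and immediate early genes rose and 3 fell (15 and 4 adjusted over the list alone). The median was 1.08 on the log2 scale, with a camera adjusted p = 0.000989 and adjusted p = 0.395 with an estimated correlation. Fos rose from 3.55 ± 0.752 to 83.8 ± 29.7 CPM (edgeR adjusted p = 6.82e-05) and Fosb from 8.27 ± 2.97 to 79.6 ± 14.7 CPM (adjusted p = 0.000157). Btg2 and Ier3 rose by 3.43 and 1.41 on the log2 scale. Srf, Nr4a1 and Myc fell, with log2 fold changes of -1.56, -1.28 and -1.03. Among 26 p53 target genes 10 rose and 3 fell (10 and 3 adjusted over the list alone). The median was 0.56 on the log2 scale, with a camera adjusted p = 0.00668 and adjusted p = 0.381 with an estimated correlation. Trp53inp1 rose from 7.79 ± 2.95 to 113 ± 29.2 CPM (edgeR adjusted p = 0.000185), Eda2r by 2.12 and Zmat3 by 0.80. Ckap2, a spindle gene, and, named after their values were seen, Trp53 itself and Dda1 fell (-1.27, -0.94 and -0.51). Apoptosis regulators did not pass camera (5 of 23 higher and 3 lower, 5 and 3 adjusted over the list alone, camera adjusted p = 0.205); Birc3 and the caspase gene Casp12 (log2 fold change 2.74) had the lowest p. Named after their values were seen, Bcl2l11, Birc2 and Bcl2l1 also rose (1.84, 1.385 and 0.78), and Bak1, Bok and Cycs fell (-1.33, -1.0 and -0.775).

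Sterol synthesis genes fell in 16 of 22 cases and rose in 1 (18 and 1 adjusted over the list alone). The median was -1.04 on the log2 scale, with a camera adjusted p = 1.05e-05 and adjusted p = 0.395 with an estimated correlation. Srebf2, the transcription factor of the pathway, went from 483 ± 41.1 to 258 ± 25.6 CPM (edgeR adjusted p = 0.00176). Knockout replicate 1 stood apart for this list. Its mean log2 level, relative to all 8 libraries, was 0.213, near the 0.337 to 0.601 of WT, against -0.537 to -0.812 in the other knockout libraries. Idi1 went from 201 ± 39.0 to 58.5 ± 27.3 CPM and Hmgcs1 from 247 ± 29.1 to 99.1 ± 34.1 CPM. Insig1, which restrains the pathway, rose from 127 ± 42.7 to 327 ± 27.8 CPM (adjusted p = 0.00246). Glycolysis and hypoxia genes fell in 9 of 25 cases and rose in 1, Pfkfb4, named after its value was seen (9 and 1 adjusted over the list alone). The median was -0.61 on the log2 scale, with a camera adjusted p = 0.00495 and adjusted p = 0.395 with an estimated correlation. Slc16a3, Pfkl (-1.24), Hk2 (-0.65) and Gapdh (-2.25) were among the decreases. Knockout replicate 1 stood apart for the glycolysis list too. Its mean log2 level was 0.015, against -0.414 to -0.531 in the other knockout libraries and 0.165 to 0.562 in WT. Gapdh has many processed pseudogenes, and its level of 153 ± 100 CPM in WT is uncertain for that reason. ATF4 and unfolded protein response genes fell in 11 of 31 cases and rose in 2 (11 and 2 adjusted over the list alone). The median was -0.33 on the log2 scale, with a camera adjusted p = 0.0352 and adjusted p = 0.540 with an estimated correlation. That call was lost without WT replicate 2 or knockout replicate 2 (adjusted p = 0.0682 and 0.139). It was also lost with annotated genes only (0.057), with the stricter filter (0.0604) and with fry (0.086). The amino acid transporter gene Slc7a5 went from 638 ± 88.9 to 217 ± 77.8 CPM, and Psat1 and Shmt2 of serine metabolism had log2 fold changes of -1.26 and -1.52. Cth and, named after its value was seen, Ddit3 rose (4.33 and 1.00). Lysosome and autophagy genes rose in 15 of 30 cases with none falling (15 and 0 adjusted over the list alone). The median was 0.63 on the log2 scale, with a camera adjusted p = 0.000124 and adjusted p = 0.395 with an estimated correlation. Examples were the cathepsin gene Ctsb (415 ± 46.4 to 984 ± 89.0 CPM), Sqstm1, Gabarapl1 and Atg9b (1.32, 1.63 and 2.94 on the log2 scale). Heat shock (1 higher and 4 lower of 17, 1 and 1 adjusted over the list alone, camera adjusted p = 0.0997) and NRF2 genes (4 and 7 of 27, 4 and 8 adjusted over the list alone, 0.287) did not pass. Neither did fatty acid synthesis (2 and 5 of 21, 2 and 5 adjusted over the list alone, 0.646) or oxidative phosphorylation genes (4 and 0 of 31, 1 and 0 adjusted over the list alone, 0.646). Within them, Aldh3a1 and Cryab rose (2.69 and 1.81), as did Ndufa1 and Ndufb3 (1.86 and 1.49), and Gclm, Elovl6, Fasn and Hsf1 fell (-1.85, -2.19, -0.91 and -0.59). The remaining calls of 5 or fewer in these lists were named after their values were seen. Cox6c, Ndufs3, Lpin1, Acadm, Gsta2, Gsta4 and Gstm1 rose (0.63, 0.62, 0.58, 0.47, 2.83, 1.485 and 0.65), and Fads2, Me1, Acaca, Hsp90aa1, Hspd1 and Hsp90ab1 fell (-1.01, -0.715, -0.47, -0.75, -0.73 and -0.68). Some of these calls moved with the setting. Heat shock passed as lower with no filter on low counts (camera adjusted p = 0.0327) and without WT replicate 2 or knockout replicate 1 (0.0462 and 0.0283). NRF2 passed as lower without knockout replicate 1 (0.0286), and Hsf1 was lost without knockout replicate 3 (edgeR adjusted p = 0.0515).

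Epithelial genes rose in 5 of 11 tested cases, of 30 listed, with none falling (6 and 0 adjusted over the list alone). The median was 1.14 on the log2 scale, with a camera adjusted p = 0.0128 and adjusted p = 0.302 with an estimated correlation. Among the increases were the keratin genes Krt7 (0.480 ± 0.135 to 8.70 ± 2.92 CPM) and Krt18 (38.5 ± 2.93 to 76.3 ± 8.65 CPM), Lgals4, Jup and, named after its value was seen, Pkp3 (1.54). In the list named intestinal differentiation, 6 of 10 tested members, of 34 listed, rose and 1 fell (6 and 1 adjusted over the list alone). The median was 1.19 on the log2 scale, with a camera adjusted p = 0.00466 and adjusted p = 0.302 with an estimated correlation. The water channel gene Aqp8 rose from 2.27 ± 2.09 to 104 ± 11.1 CPM (edgeR adjusted p = 0.000821). Clu rose from 10.7 ± 3.43 to 78.5 ± 10.9 CPM and Ly6a, the Sca-1 surface antigen gene, from 4.94 ± 3.02 to 53.3 ± 23.8 CPM. The intestinal list also holds stem cell genes such as Lgr5 and Ascl2, and Clu and Ly6a do not mark differentiated cells. A rise of this list therefore does not show differentiation. Collagen and matrix genes rose in 11 of 35 cases and fell in 1, Lamb3 (11 and 1 adjusted over the list alone). The median was 0.38 on the log2 scale, with a camera adjusted p = 0.0301 and adjusted p = 0.395 with an estimated correlation. Col6a1 rose from 9.21 ± 2.54 to 55.9 ± 6.78 CPM, and Thbs2 and Col18a1 by 2.10 and 1.70 on the log2 scale. Dcn had 4 counts in WT, all in replicate 4, against 1047 in the knockout libraries. Its fitted log2 fold change of 7.65 is loosely fixed for that reason, from 7.195 to 10.925 with 1 library left out, the top value without WT replicate 4, when WT is at 0 and the prior count sets it. Integrin, focal adhesion and actin genes fell in 10 of 37 cases and rose in 3 (10 and 3 adjusted over the list alone). The median was -0.27 on the log2 scale, with a camera adjusted p = 0.00802 and adjusted p = 0.395 with an estimated correlation. The tropomyosin gene Tpm4 and the focal adhesion kinase gene Ptk2 fell (-1.24 and -0.76), while Tns1, Rhob and, named after its value was seen, Itgb5 rose (1.72, 1.503 and 0.80). Of the remaining lists of this kind, 5 did not pass camera. They were mesenchymal genes (7 of 25 higher, 2 lower, 7 and 2 adjusted over the list alone, camera adjusted p = 0.263) and the TGF-beta and BMP response (6 and 2 of 24, 6 and 2 adjusted over the list alone, 0.388). The others were Wnt targets (2 and 4 of 10, 3 and 4 adjusted over the list alone, 0.469), Notch (2 and 3 of 10, 3 and 3 adjusted over the list alone, 0.818) and growth factors and receptor tyrosine kinases (11 and 1 of 31, 11 and 1 adjusted over the list alone, 0.0997). The last of these passed as higher with the replicate block (adjusted p = 0.0409), the stricter filter (0.0443), the GC and length trend removed (0.0302), fry (0.0489) and without knockout replicate 1 (0.0318). Tgfbi, Mmp13, Smad3, Wnt10a, Pdgfra, Igfbp4 and Notch4 rose (2.97, 3.09, 1.61, 2.47, 2.16, 1.95 and 1.35). Ephb2 fell (-1.03), and Mfng, at 0 in all WT libraries, was at least 42.2-fold higher. Among the called members named after their values were seen, Sox4 rose (1.13), Cdh2, Mmp14, Pmepa1 and Ltbp2 fell (-1.08, -0.80, -1.79 and -1.67), and so did Lef1, Apcdd1, Znrf3, Hes1, Rfng, Nrarp and Met (-1.335, -1.01, -0.75, -1.10, -1.05, -0.52 and -0.51). The median and the camera direction had opposite signs for the YAP target, TGF-beta, Notch, neural and mitochondrially encoded lists.

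Among the fibroblast, muscle and neural marker lists only that of fibroblasts passed camera. Fibroblast markers rose in 7 of 10 tested cases, of 16 listed, with none falling (7 and 0 adjusted over the list alone). The median was 2.18 on the log2 scale, with a camera adjusted p = 0.00784 and adjusted p = 0.395 with an estimated correlation. Col3a1 rose from 31.3 ± 21.1 to 143 ± 60.5 CPM and Mfap5 from 0.0368 ± 0.0736 to 1.52 ± 0.434 CPM. Mfap5 had 4 counts in WT, all in replicate 1, and its log2 fold change lay between 4.857 and 8.566 with 1 library left out, the top value being set by the prior count with WT at 0. Muscle markers (4 of 6 higher, 0 lower, 4 and 0 adjusted over the list alone, camera adjusted p = 0.114) and neural markers (1 and 1 of 9, 1 and 1 adjusted over the list alone, 0.871) did not pass, though muscle did with no filter on low counts (0.0327) and with fry (0.00292). Their called members included Des and Nppb, up by 3.33 and 3.797, Syt1, up by 1.43, and Nes, at -1.23. Mylpf and Tnnc1, named after their values were seen, rose by 1.61 and 1.25. Too few members were tested for camera in the lists of macrophage (3 of 4 higher), lymphocyte (1 of 2), endothelial (3 of 3) and keratinocyte (3 of 3) markers. Adjusting over the list alone gave the same counts. These lists were fixed with 19, 20, 14 and 18 members, most of which were not tested. A marker near 0 in WT passes the filter on low counts only through the knockout libraries. The shares of tested members that rose are therefore partly set by the filter. The macrophage markers Cd14 and Cd68 were at 53.02 ± 9.72 and 11.2 ± 1.62 CPM in the knockout libraries, and the endothelial markers Tie1 and Vwf at 4.11 ± 1.59 and 5.58 ± 3.98 CPM. The keratinocyte markers Sfn and Lgals7 were at 2.58 ± 0.355 and 22.7 ± 5.49 CPM, and the lymphocyte markers Coro1a and Lck at 0.911 ± 0.739 and 2.24 ± 0.328 CPM, Lck not passing (adjusted p = 0.504). Lyz2, Eng and Trp63, named after their values were seen, rose by 3.21, 0.945 and 3.38. The call for Coro1a was lost without knockout replicate 2 (adjusted p = 0.0681), and that for Lgals7 without WT replicate 4 or knockout replicate 3 or 4 (0.0611, 0.0562 and 0.0622).

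Measures of RNA and library quality also differed. Cytoplasmic ribosomal protein genes rose in 8 of 31 cases and fell in 1, Rps2, named after its value was seen (8 and 1 adjusted over the list alone). The median was 0.50 on the log2 scale, with a camera adjusted p = 0.000684 and adjusted p = 0.536 with an estimated correlation. All rows with a symbol of Rpl or Rps followed by a digit, a set that differs from the list, were also summed. They took 5.27 ± 0.311% of counts in the knockout libraries and 3.36 ± 0.848% in WT (SD, n = 4). Rpl23 rose by 1.44 and Rpl37 by 2.17, with ranges of 1.369 to 1.505 and 1.897 to 2.79 when 1 library was left out. The call for Rpl32 was lost with the GC and length trend removed and that for Rps23 without WT replicate 4 (edgeR adjusted p = 0.0650 and 0.0595). These genes have many pseudogenes and their levels are uncertain. Of 13 mitochondrially encoded transcripts none passed edgeR's test over all genes or adjusted over the list alone (camera adjusted p = 0.808, adjusted p = 0.924 with an estimated correlation). Their share of counts was 1.05, 3.99, 3.11 and 0.904% in WT replicates 1 to 4 and 4.17, 4.89, 0.135 and 5.29% in knockout replicates 1 to 4. Without knockout replicate 3 the list passed camera as higher (adjusted p = 0.0113).

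**Figure D4:**
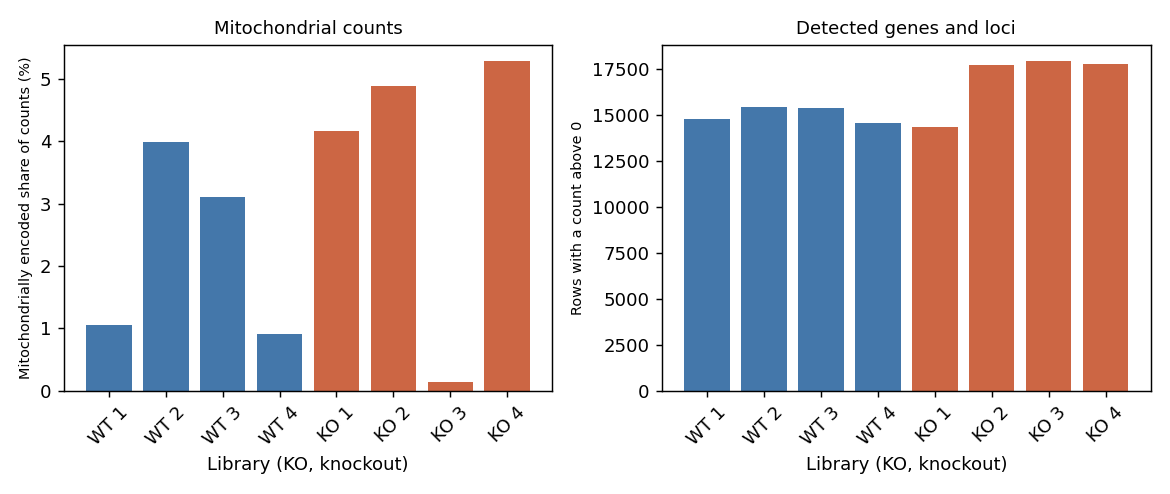
Share of counts from mitochondrially encoded genes in percent (left) and number of genes and loci with a count above 0 (right), as bars from 0, for each WT (blue) and knockout (orange, KO) library. Knockout replicate 3 has 0.135% mitochondrially encoded counts, and knockout replicate 1 has 14345 detected genes and loci against 17759 or more in the other knockout libraries.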

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

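Within each genotype of 4 libraries, a value was singled out when its gap to the nearest other library exceeded Dixon's 95% critical share of the whole range. Of 372 groups of values, 39 met this, where chance gives about 1 in 20, or 18.6, and 19 of the 39 lay in knockout replicate 1. The tests of mitochondrial read loss and of leukocytes, and the spread over libraries used for the interferon genes, were chosen only after the results were seen.

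Knockout replicate 1 had 14345 rows with a count above 0, against 17759 to 17948 in the other knockout libraries. It was the lowest knockout library for C3 (32.1 CPM), Crim1 (194.8), Ifih1 (53.4), Gbp4 (19.9), H2-T22 (91.0), H2-T23 (13.8), Thbs2 (96.0), Smad3 (125.9) and Igfbp4 (270.8), and the highest for Srm (282 CPM), Pfkl (111.4), Gclm (147) and Hsf1 (91.5). On the scale of mean log2 CPM relative to all 8 libraries it was lowest for the interferon gamma list (0.91) and the TGF-beta list (-0.29), and highest for the MYC target (-0.051), integrin and actin (-0.10) and cytoplasmic ribosomal protein lists (0.57). Knockout replicate 2 was highest for Mmp3 (32.0 CPM), Cryab (73.4), Cd14 (67.5) and the apoptosis list (0.25), and lowest for Arsj (2.71 CPM) and the ATF4 list (-0.60). Knockout replicate 4 was lowest for Insig1 (285.7 CPM) and Cd68 (8.77).

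In WT, replicate 4 was lowest for Agt (0 CPM), Casp12 (0.816) and the chemokine list (-1.24) and highest for Fosb (12.7 CPM) and Dcn (0.142). WT replicate 3 was lowest for Pole (127.8 CPM) and highest for Tie1 (0.337), WT replicate 2 highest for Slco2b1 (0.0683) and WT replicate 1 highest for Mfap5 (0.147); for Dcn, Tie1, Slco2b1 and Mfap5 the other WT libraries were at 0.

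Knockout replicate 3 held far fewer mitochondrially encoded counts than the other libraries: mt-Co2 was at 80.9 CPM (2818 to 3449 in the other knockout libraries), mt-Co3 at 56.5 CPM (2233 to 3047), and the list of 13 at -3.91. Each of the 13 transcripts was lower by 13.2- to 48.8-fold (median 37.9) than in the other 3 knockout libraries. The gap to WT replicates 1 and 4 was smaller: mt-Nd3 was at 3.23 CPM against 5.04 and 4.90, and mt-Co3 at 56.5 against 148 and 159. Nuclear genes of oxidative phosphorylation differed between knockout replicates 3 and 4 by a median of 0.075 on the log2 scale. That is the value a loss in preparation or processing would give. A loss of mitochondrially encoded transcripts in the cells need not lower nuclear ones either, so the value cannot tell the explanations apart. One common factor on all mitochondrially encoded reads cannot be told apart from gene-specific loss: the SD of the shift over the 13 genes was 0.518, against at most 0.403 in the other knockout libraries. No biological explanation was tested, since knockout replicate 3 shares its group with 3 libraries that lack the pattern.

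The rise of the type I interferon list was set against the growth state of the cultures, read as the level of the G2/M list. With that level as a covariate, the 31 members called without it kept a median share of 0.787 of their log2 fold change (95% bootstrap interval over members 0.76 to 0.827), but only 4 members were still called (median of the list 2.66 before and 2.10 after). The covariate moves with genotype, which can widen the errors, but the cause of the lost calls was not tested. The bound of 0.75 set in advance was passed, but an interval over genes leaves out the spread between libraries: the share was 0.459 without knockout replicate 1 and 0.751 to 0.849 without each of the others, so a part played by growth state cannot be told apart from genotype. Leukocytes in the knockout cultures are argued against: their 37 macrophage and lymphocyte markers had a median of 0.033 CPM (scaled by total counts only) in the knockout libraries, 2 exceeding 10 CPM (Cd14, 56.5, and Cd68, 11.9), and Ptprc stood at 0.016 CPM; the knockout itself, or a difference between lines that arose while it was made, stays open and was not tested.

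The fall of the G2/M list did not come from scaling or from a trend with GC content or transcript length as the whole cause: its median log2 fold change stayed between -1.57 and -1.42 under 4 scalings and was -1.60 with the trend removed. Knockout replicate 1 had lost least of it and had the strongest trend with transcript length (Spearman -0.452 across genes, which are not independent replicates). Culture density at harvest is not analysed here and stays open beside the knockout.

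Of the 35 splits of the 8 libraries into 4 and 4, only the real one called any gene (5513 changed, highest other 0). The same held for genes higher (2779, highest other 0), lower (2734, highest other 0) or changed at least 2-fold (2969, highest other 0). However, the groups of the other 34 splits mix the genotypes, so the genotype difference adds to their within-group spread and lowers their counts. A rank of 1 of 35 is also the best that these splits can give. They therefore do not show what chance alone would call, and do not exclude chance. Chance cannot be excluded for the count of lists either: 3 of 35 splits put at least 21 past camera, and the highest of the others was 23. Every other split mixes the genotypes, so its count is not that of unchanged libraries: both splits at 23 set 3 WT libraries and 1 knockout library against the rest and keep part of the genotype contrast, while splits with 2 libraries of each genotype on either side gave 6 to 15 lists, and counts simulated without change gave 0. That simulation drew each gene independently, while the correlation estimated in the real data was 0.647 for the type I interferon list and 0.914 for G2/M. Its 0 is therefore not the count that unchanged but correlated genes would give.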

How the results depend on the processing

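Annotated-only rows, mitochondrial genes left out, the G2/M covariate and the GC and length trend were chosen after seeing the data. The numbers of genes changed stayed within 1.5 times the main count with DESeq2's size factors (5567), upper-quartile factors (5542), library size only (5475), no filter (5423), a stricter filter (4445), DESeq2's Wald test (6520), limma-voom (5698), annotated genes only (4980), without mitochondrial genes (5509) and with the GC and length trend removed (5655). Of the 141 named genes, 135 passed. All 141 kept their direction and side of the threshold under DESeq2's size factors, DESeq2's test, limma-voom and no filter. Most were named for a small p or a large change, so this was partly fixed by the choice. Of all main calls, 99.6% were kept with DESeq2's size factors, 99.5% with DESeq2's test, 96.6% with limma-voom and 89.8% with no filter. Without each library in turn, 3809 to 6829 genes changed, 2041 to 3420 higher and 1768 to 3409 lower, with 2393 to 3901 changed at least 2-fold. Tead1 ranged from -1.77 to -1.33 (adjusted p 0.00241 to 0.0102) and Tead4 from -0.83 to -0.57, the latter with adjusted p from 0.0197 to 0.0800.

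An adjusted p under 0.01 left 2736 genes (1488 higher, 1248 lower), by construction. With the G2/M covariate 555 genes were called (454 higher, 101 lower, 516 at least 2-fold), 505 of them also called without it, and 77 of the 141 named genes lost their call. Tead1 was then at -2.004 (adjusted p = 0.0719) and Tead4 at -1.06 (adjusted p = 0.143), larger sizes with higher adjusted p. The stricter filter, which tests 10262 rows, left 1880 genes changed at least 2-fold. Tead4 was at -0.51 (adjusted p = 0.0692) with upper-quartile factors and at -0.51 (adjusted p = 0.0800) with library size only, scalings that move the median of all rows to 0.20. Tead2 turned positive with upper-quartile factors (0.103), library size only (0.10), the stricter filter (0.01) and the covariate (0.304), and Wwtr1 turned negative with the covariate (-0.19); left-out libraries gave Tead2 from -0.19 to 0.016 and Wwtr1 from -0.053 to 0.178. None of these passed the test, and the cause was not tested.

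The count of lists past camera was 0 with an estimated correlation. That correlation was 0.647 for type I interferon, 0.872 for G1/S and 0.914 for G2/M genes, against the preset 0.01. A higher correlation weakens camera's test. Calls were also lost at -0.072 (epithelial genes) and 0.012 (intestinal differentiation), so its size does not account for every loss. The count was 19 to 25 under the other planned settings except for left-out libraries (20 to 24), and 15 to 22 under the added ones. Lists whose direction turned did so with these adjusted p, of camera unless fry is named, and the cause was not tested. With the covariate they were TGF-beta (0.417), growth factors (0.474), fatty acid synthesis (0.602), NRF2 (0.316) and mitochondrially encoded transcripts (0.417). With the stricter filter they were YAP targets (0.787), Notch (0.813) and fatty acid synthesis (0.986), and with no filter Notch (0.941) and neural markers (0.743). With the trend removed they were oxidative phosphorylation (0.782) and neural markers (0.932), and with fry neural markers (0.753). Left-out libraries gave adjusted p from 0.573 to 0.960 for YAP targets, 0.593 to 0.919 for Notch, 0.221 to 0.930 for oxidative phosphorylation, 0.675 to 0.964 for neural markers and 0.0113 to 0.995 for mitochondrially encoded transcripts.

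Libraries that share a replicate number did not deviate together over all genes (correlations -0.019, -0.017, -0.003 and -0.032 for numbers 1 to 4). This gave no sign of pairing by number. Each is 1 value over all genes, so a shared culture or preparation cannot be excluded. With the replicate block 4683 genes were called, 4525 of them also without it. At this depth and spread the simulation recovered 2% of 1.5-fold and 36% of 2-fold changes. It changed far fewer genes than were called in the real data and drew each gene independently. These shares therefore do not give the sensitivity in the real data.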

Other observations

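6 annotated genes past the threshold had no count in any knockout library, and they were named after their values were seen. Lonrf1 (chromosome 8, 36216064 to 36249516, minus strand) was at 4.54 ± 0.679 CPM in WT, at least 49.7-fold lower in the knockout libraries against 3 counts per library (edgeR adjusted p = 0.000258). Hcn2, a pacemaker channel gene (chromosome 10, 79716634 to 79736108, plus strand), was at 3.56 ± 0.690 CPM in WT and at least 39.0-fold lower. Dpyd, the enzyme that breaks down pyrimidines and 5-fluorouracil (chromosome 3, 118562129 to 119432924, plus strand), was at 2.24 ± 0.527 CPM and at least 24.5-fold lower (edgeR adjusted p = 0.000552). Mypn, Syde2 and Zfp810 were at 2.05 ± 0.790, 1.94 ± 0.510 and 1.21 ± 0.793 CPM in WT and at least 22.4-, 21.2- and 13.3-fold lower. In the other direction, 43 genes and loci past the threshold, 26 of them annotated, had no count in any WT library.

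The median log2 fold change by chromosome lay between -0.29 on chromosome 3 (575 genes, 81 higher and 214 lower) and 0.15 on chromosome 5 (764 genes, 196 higher and 136 lower). Chromosome 8 was close to chromosome 3, with -0.28 over 636 genes, 73 of them higher and 217 lower. These were not singular: 16 of 20 chromosomes lay outside the central 95% of 10000 random gene sets of the same size, which treat genes as independent. Chromosomes 1 (median -0.18, 112 higher and 186 lower), 3 and 8 lay below all random sets, and chromosomes 2 (0.117) and 5 above all.

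Some libraries of 1 genotype differed along the same axis as the genotypes. The first principal component took 67.6% of the variance, with WT replicates at -86.6, -43.0, -45.2 and -95.5 and knockout replicates at 37.2, 71.5, 81.4 and 80.1. Across genes, which are not independent replicates, WT replicate 2 minus 4 correlated at 0.413 with the contrast computed from the other libraries, WT 3 minus 4 at 0.393, WT 1 minus 2 at -0.371 and WT 1 minus 3 at -0.348. Knockout replicate 1 minus 2, 3 and 4 correlated at -0.419, -0.449 and -0.422. The other 5 pairs showed little of this, with correlations from -0.143 to 0.081.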
